A study of Mus musculus with 2 samples.

How the data were processed

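RNA from cultured splenic B cells was sequenced for 1 Nedd4+/+ and 1 Nedd4-/- library. Per the labels, cells from fetal liver chimeric mice were grown for 72 hours with LPS and IL-4, ribosomal RNA was removed with a Ribo-Zero kit, and libraries followed the standard Illumina procedure. Groups were taken from the titles, and the labels tell of no second culture or animal per genotype.

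TopHat, Cufflinks and the mouse build mm9 are named per the submitters' processing notes, with no version and no statement of which step each served. The strand setting, the treatment of reads with several matches and the settings of the counting step are not given in the sources used here. Per the file headers, the deposited gene values are RPKM, for 1 RefSeq transcript on each of 23288 lines. The values are whole multiples of 1 constant per library over the bases of a transcript in part of the low genes: 50.6% of 4994 values tested in the Nedd4+/+ library and 56.4% of 3762 in the Nedd4-/- library came out whole within 0.02 bases. They were read as the mean depth per base times that constant.

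The second deposited column is named for the upstream kb only, per the file headers, and the values show it to be a ratio: the level of the window divided by the gene's RPKM plus 0.0001. Multiplying the deposited ratio by the gene's RPKM plus 0.0001 gave whole numbers of read bases in a window of 1000 nt for 100% of 12619 low windows in the Nedd4+/+ library and 100% of 13554 in the Nedd4-/- library, within 0.05 bases. The design had assumed a level in this column. The upstream level used here is therefore that product, in RPKM, and all planned comparisons were run on it. Without this step a gene with a lower level would show a higher upstream value.

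Depth was recovered from the same steps. The most common base counts of the windows were multiples of 101, which was taken as the read length in nt. The values corresponded to 8.40 gigabases of reads in the Nedd4+/+ library and 6.16 gigabases in the Nedd4-/- library. The 22622 transcripts with a known length held 32.6% and 24.4% of these bases. Of all genes, 9525 and 9268 had at least 1 RPKM, and 432 and 219 were listed at 0. Recovered bases were divided by the length of a read pair, which need not give whole numbers. Counting intervals are exact Clopper-Pearson 95% intervals on these numbers of pairs, without pseudocount. They cover counting error only, since reads without molecular identifiers are not independent molecules.

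Gene comparisons used log2((Nedd4-/- + 1)/(Nedd4+/+ + 1)) in RPKM among genes with a mean of 1 RPKM or more and a fixed rule of at least 2-fold. This scale understates the difference of low genes. Upstream comparisons added 0.1 RPKM and used windows with a mean of 0.2 RPKM or more. With 1 library per group no p-value was computed.

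For each of 34 gene lists the median log2 ratio was placed among 10000 seeded random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5. Lists with fewer than 5 tested members got values only. Percentiles describe these libraries and do not test genotype. The lists covered AID off-target genes, CSR factors, AID cofactors, the RNA exosome, RNA polymerase II, Nedd4 relatives, snoRNA hosts, structured noncoding RNAs, histones, ribosomal proteins, oxidative phosphorylation, cell cycle, p53 targets, antibody secretion, mature B cells, marginal zone and B1 cells, germinal center, IL-4, LPS and NF-kappaB, interferon, MHC class II, immunoglobulin genes, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, immediate early genes, apoptosis, T cells, natural killer and innate lymphoid cells, myeloid cells, mast cells and basophils, erythroid cells and megakaryocytes, stromal and endothelial cells, and sex-linked genes.

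The comparisons, lists, thresholds and the rule for naming genes were set before the data were examined. Named are Nedd4, and the 12 highest and 12 lowest log2 ratios among genes with a mean of 5 RPKM or more. Small RNA genes (by symbol prefix, or transcripts under 300 nt), predicted symbols and genes without a symbol were left out of these. Also named are up to 4 members per list with the largest absolute log2 ratio among members of 1 RPKM or more, the 8 highest and 8 lowest upstream ratios among windows with a mean of 1 RPKM or more, with the same exclusions, and the off-target genes with an upstream mean of 0.2 RPKM or more. Of these, the text gives the members that show the range of each list, and some genes that the rule takes are not reported here. H2-Aa, Thy1, Uty, Kdm5d, Myo1e, Aqp9, Dapk2, Snhg12, Snhg1, genes named relative to a median and the upstream windows of Ier3, Klf2 and Egr2 were named after their values were seen.

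The reference at hand was build GRCm38 and not mm9, so it served only for names, neighbours, transcript length and GC content. Of the genes, 23200 (99.6%) were matched to it. No coordinates are given, and distances to Nedd4 and the 7823 windows overlapping another gene come from that build.

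Alternatives set in advance were pseudocounts of 0.1 and 5 RPKM, no minimum and a minimum of 5 RPKM, rescaling to a median or trimmed mean log2 ratio of 0, folds of 3 and 1.5, and leaving out small RNA genes. Upstream, they were pseudocounts of 0.02 and 1 RPKM, no minimum and a minimum of 1 RPKM, rescaling, leaving out windows that overlap another gene, unmatched random lists, and a distance of 20 Mb. Chosen after seeing the data were a subtraction of each library's background, random lists matched on GC content or length, and leaving out genes over a depth of 2000 reads per base or on the X and Y chromosomes. The background of a library was its median level at 12310 genes with a mean under 0.5 RPKM.

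The procedure was tested on simulated libraries of these depths over 22622 genes. Of 50 genes changed at each size, 0% passed the rule in the right direction at 1.5-fold, 98% at 2.5-fold and 100% at 4-fold and at 8-fold. Of 9046 unchanged genes tested, 10 passed it. The simulation held counting error only, around a shared level per gene. It had no variation between cultures and no difference in background or median ratio, so these 10 do not give the rate of wrong calls in the real libraries. Of 200 unchanged lists 3.5% stood apart, and 100% of 50 lists shifted by 0.5 on the log2 scale did. List members were drawn at random from that simulation, so these shares do not give error rates for lists of related genes. Read bases were recovered in 100% of 13849 simulated windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.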

Results

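RNA was measured in cultured splenic B cells from fetal liver chimeric mice, animals whose blood cells derive from transplanted fetal liver. 1 library came from Nedd4+/+ cells and 1 from Nedd4-/- cells. Nedd4 encodes a ubiquitin ligase of the HECT class, an enzyme that attaches ubiquitin to other proteins. The cells had been cultured for 72 hours with lipopolysaccharide (LPS), a bacterial cell wall component that activates B cells, and the cytokine interleukin 4 (IL-4). This combination drives class switch recombination to IgG1, in which the cytidine deaminase AID acts on transcribed DNA. RNA depleted of ribosomal RNA was sequenced, so that noncoding and unspliced transcripts were sampled beside messenger RNA. Each of 23288 genes had a level in RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library) and a level for the 1 kb upstream of the gene. The values corresponded to 8.40 gigabases of 101-nt reads in the Nedd4+/+ library and 6.16 gigabases in the Nedd4-/- library. Without a replicate in either group no difference has a replicate check and no test of genotype was made. Intervals given here are exact Clopper-Pearson 95% intervals of the reads and cover counting error only.

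The first comparison asked how gene levels differed between Nedd4-/- and Nedd4+/+ B cells. Nedd4 itself, on chromosome 9, stood at 7.59 RPKM in the Nedd4+/+ library and at 1.95 RPKM in the Nedd4-/- library, a log2 ratio of -1.54 on the RPKM + 1 scale used throughout. The ratio without the pseudocount had a counting interval of -2.13 to -1.79 on the log2 scale. Log2 levels in the libraries had a Pearson correlation across genes of 0.990, where genes are not independent replicates. Of 9405 genes with a mean of 1 RPKM or more, 13 were at least 2-fold higher in the Nedd4-/- library and 108 at least 2-fold lower. The median log2 ratio of these genes was -0.31, however, and the central 90 percent ran from -0.74 to 0.06. Relative to that median, 26 genes were at least 2-fold higher and 21 at least 2-fold lower, which moved the share of higher genes among those passing from 10.7% to 55.3%. Nedd4 was at -1.23 relative to the median. Below, a relative value is a log2 ratio minus that median. RPKM is scaled to all mapped reads, and transcripts of known length held 32.6% of the bases in the Nedd4+/+ and 24.4% in the Nedd4-/- library. Log2 ratios not given as relative include this difference between the libraries.

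**Figure D1:**
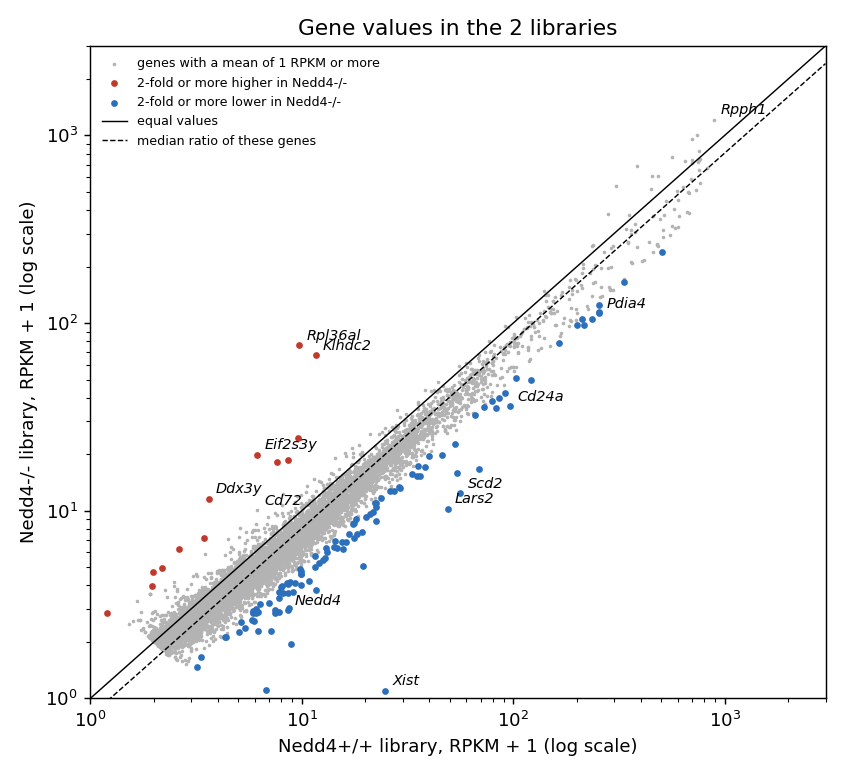
Level of each gene in the Nedd4+/+ library (x axis, RPKM + 1, log scale) against the Nedd4-/- library (y axis, RPKM + 1, log scale), 1 point per gene with a mean of 1 RPKM or more. Colours mark the 13 genes at least 2-fold higher and the 108 at least 2-fold lower in the Nedd4-/- library; the dashed line is the median log2 ratio of -0.31, which lies under the line of equal values.

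Among the named genes higher in the Nedd4-/- library, 5 were neighbours on chromosome 12. Rpl36al, a ribosomal protein gene, stood at 8.71 RPKM in the Nedd4+/+ library and had a log2 ratio of 2.97 (counting interval without pseudocount 2.88 to 3.33). Klhdc2, which encodes a substrate receptor of a ubiquitin ligase, stood at 10.6 and 66.2 RPKM, a log2 ratio of 2.53. The others were Mgat2, an enzyme of N-glycan processing (1.34), Dnaaf2, an assembly factor of ciliary dynein (1.25), and Pole2, a subunit of DNA polymerase epsilon (1.11). Cd72, a receptor on B cells, was at 5.12 and 9.04 RPKM (0.71), Slc37a2 had a log2 ratio of 0.65, and Casp1, the protease that activates interleukin 1 beta, 0.53. Rpph1 and Vaultrc5, structured noncoding RNAs, had log2 ratios of 0.45 and 0.44 but the same depth in both libraries. Rpph1 had a mean of 7454 and 7463 reads per base and Vaultrc5 2353 and 2349, where the difference in library size alone gives an RPKM ratio of 1.36, or 0.45 on the log2 scale. Their values may be capped and are not read as a difference in RNA.

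The named genes lower in the Nedd4-/- library included genes of lipid synthesis and of the B cell surface. Scd2 and Scd1, desaturases that make monounsaturated fatty acids, stood at 55.3 against 11.4 RPKM (log2 ratio -2.18) and at 53.1 against 15.0 RPKM (-1.76). Fdps and Lss, enzymes of sterol synthesis, had log2 ratios of -1.33 and -1.32. Cd24a, a surface glycoprotein, was at 95.9 and 35.0 RPKM (-1.43). Sla, an adaptor of antigen receptor signalling, had a log2 ratio of -1.63, Bank1, a scaffold of B cell receptor signalling, -1.35, and Fcrl5, a receptor of the Fc receptor-like family, -1.31. Derl3, of endoplasmic reticulum-associated degradation, had a log2 ratio of -1.36. Lars2, the mitochondrial leucyl-tRNA synthetase, was at 48.0 and 9.24 RPKM (-2.26).

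Sex-linked genes also differed, and Xist had the widest log2 ratio of any gene tested. Xist, the RNA that coats the inactive X chromosome, stood at 23.7 RPKM in the Nedd4+/+ library and at 0.0958 RPKM in the Nedd4-/- library, a log2 ratio of -4.50. Its antisense partner Tsix was at 5.78 and 0.107 RPKM, and without strand the reads of this pair cannot be told apart. The Y-linked genes Eif2s3y and Ddx3y were at 5.14 against 18.8 RPKM (1.69) and 2.63 against 10.6 RPKM (1.68), and Uty and Kdm5d also passed the 2-fold rule. The Nedd4+/+ library thus held both Xist and Y-linked transcripts, with Y-linked levels between 24.8% and 31.0% of those in the Nedd4-/- library. This sex-linked difference lies between the same libraries as every other difference given here. With 1 library per genotype, its effects cannot be told apart from those of genotype in any of them. Of 10 sex-linked genes, 6 were tested, with a median log2 ratio of 1.22 (percentile 100 among matched random lists). The list pools 4 Y-linked genes that were higher with Xist and Tsix, which were lower. Its median and percentile therefore reflect which kind of gene is more numerous in it.

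Genes of antibody secretion and of protein folding in the endoplasmic reticulum were lower as a group in the Nedd4-/- library. Of 28 tested genes of plasmablasts and antibody secretion, 27 lay below the median of all genes and 7 were at least 2-fold lower, or 1 relative to that median, Derl3. They included Txndc5 and Pdia4, disulfide isomerases, at 81.9 against 34.1 RPKM (-1.24) and 255 against 112 RPKM (-1.18). Igj, the joining chain of polymeric antibodies, was at 216 and 96.4 RPKM (-1.15). Among genes of the unfolded protein response, all 20 tested lay below the median of all genes and 5 were at least 2-fold lower, or 0 relative to that median. Examples were Asns, asparagine synthetase (-1.22), Ero1lb, an oxidase of disulfide formation (-1.14), and Hyou1, a chaperone (-1.10). The secretion list had a median log2 ratio of -0.86 and a relative median of -0.55, and the unfolded protein list -0.83 and -0.52. Both medians lay at percentile 0 of 10000 random lists of equal size matched on expression. The lists share 8 genes and are not independent of each other.

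Genes of cholesterol synthesis, of glycolysis and of replication-dependent histones were also lower as groups. All 22 tested genes of cholesterol synthesis lay below the median of all genes and 7 were at least 2-fold lower, or 2 relative to that median, Fdps and Lss. Others were Mvd, a decarboxylase of the mevalonate pathway (-1.25), and Insig1, a regulator of sterol sensing (-1.25). Of 29 glycolytic and hypoxia-inducible genes, 28 lay below the median and 11 were at least 2-fold lower, or 1 relative to that median, Bnip3. The furthest were Bnip3, a mitophagy receptor, at 6.81 and 1.90 RPKM (-1.43), the growth factor gene Vegfa (-1.20), Ankrd37 (-1.18) and the glucose transporter gene Slc2a1 (-1.14). Of 65 histone genes, 58 lay below the median and 7 were at least 2-fold lower, or 0 relative to that median, with Hist1h1e at 120 and 48.6 RPKM (-1.29), Hist1h1c at -1.17 and Hist1h2ak at -1.16. Histone genes are near-identical copies, so reads cannot be assigned to each with certainty. The medians were -0.91 for cholesterol synthesis, -0.93 for glycolysis and -0.82 for histones, or -0.60, -0.61 and -0.50 relative to all genes, each at percentile 0. Genes of S phase and mitosis did not stand apart with the histones: 43 were tested, with a median of -0.37 at percentile 68.6, and Mki67, the proliferation marker, had a log2 ratio of -0.77.

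**Figure D2:**
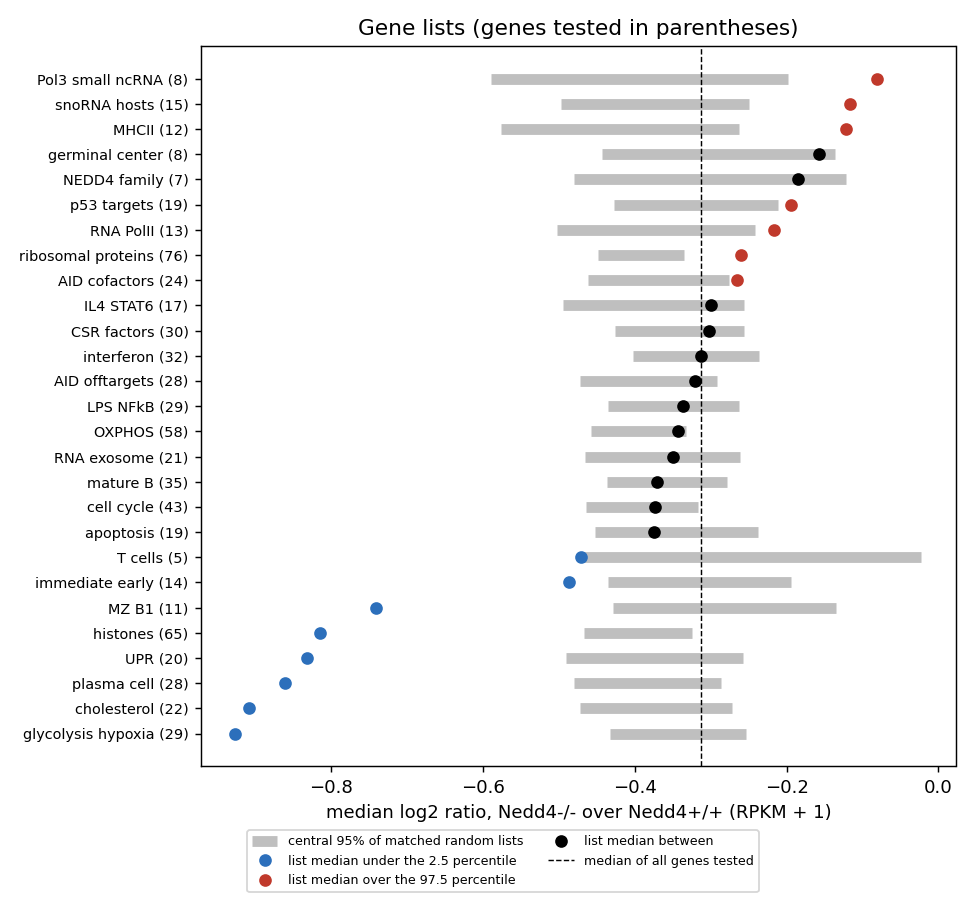
Median log2 ratio of each gene list (points; x axis, log2 of RPKM + 1, Nedd4-/- over Nedd4+/+) with the central 95% of 10000 matched random lists (grey bars); the number of genes tested is in parentheses and the sex-linked list, at 1.22, is left out. Glycolysis, cholesterol synthesis, antibody secretion, the unfolded protein response and histones lie furthest to the left, between -0.93 and -0.82.

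Genes of B cell subsets differed in both directions. Of 11 tested genes of marginal zone and B1 cells, 8 lay below the median of all genes, including the scavenger receptor gene Cd36 (-0.94), Dtx1, a Notch pathway gene (-0.92), Plac8 (-0.90) and the transcription factor gene Bhlhe41 (-0.84). Their median of -0.74 lay at percentile 0. Genes of antigen presentation on MHC class II lay above matched genes, with a median of -0.12 as deposited, 0.19 relative to all genes, at percentile 99.99. H2-Aa, an MHC class II chain, was at 353 and 377 RPKM, whereas H2-DMb2, a chain of the peptide-loading factor, was at 108 and 74.8 RPKM (-0.53). Of 35 genes of mature B cell identity 3 were at least 2-fold lower, among them Bank1 and the chemokine receptor gene Cxcr5 (-1.03), while the kinase gene Syk was at -0.96. Their median of -0.37 lay at percentile 36.2. Germinal center genes had a median of -0.16 over 8 genes at percentile 95.7, with Gm600 at -0.80, Plxnb2 at -0.45 and Fas, a death receptor gene, at 0.20.

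Responses to the culture stimuli mostly did not stand apart. IL-4-inducible genes had a median of -0.30 over 17 genes (percentile 87.8), although Socs3, a feedback inhibitor of cytokine signalling, was at 8.96 and 3.04 RPKM (-1.30) and the transcription factor gene Nfil3 at -0.72. Genes induced by LPS and NF-kappaB had a median of -0.34 over 29 genes (percentile 58.4). Of these, 14 lay above the median of all genes and 15 below, among the latter the cytokine gene Il6 at -0.80 and the NF-kappaB inhibitor Tnfaip3 at -0.73. Interferon-inducible genes had a median of -0.31 over 32 genes (percentile 54.4), with 2 at least 2-fold lower, the nucleic acid sensor gene Zbp1 (-1.24) and Ifi27l2a (-1.04), or 0 relative to the median of all genes. Immediate early genes did stand apart, at -0.49 over 14 genes (percentile 0.36), with Atf3 at -0.82, Junb at -0.77 and Jund at -0.73. Their percentile was 35.0 without a minimum level and 39.0 with a minimum of 5 RPKM. Regulators of apoptosis had a median of -0.38 over 19 genes (percentile 28.6), with Bcl2 at -0.73 and Bak1 at -0.72. Target genes of p53 had a median of -0.19 over 19 genes (percentile 98.7). Of these, 14 lay above the median of all genes, among them Fas (0.20), and 5 below. The furthest members, Trp53inp1 at -0.86 and Sesn2 at -0.72, were among the 5. The percentile of the p53 targets was 87.1 with a minimum of 5 RPKM.

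Genes of class switching and of the AID machinery differed little from other genes. No CSR factor among 30 tested passed the 2-fold rule. Their median was -0.30 (percentile 80.3), with H2afx, the histone variant marked at DNA breaks, at 139 and 81.7 RPKM (-0.75), the repair genes Parp1 at -0.58 and Rad50 at -0.56. Genes known as off-target sites of AID had a median of -0.32 over 28 genes (percentile 90.4), none of them past the 2-fold rule, with the transcription factor gene Irf4 at 72.1 and 35.8 RPKM (-0.99) and the kinase gene Pim1 at 89.7 and 46.0 RPKM (-0.95). Subunits and cofactors of the RNA exosome, the complex that degrades RNA from its 3' end, had a median of -0.35 over 21 genes (percentile 59.3), with Exosc3 at -0.54 and Exosc5 at -0.43. AID cofactors had a median of -0.27 over 24 genes (percentile 98.6). Of these, 14 lay above the median of all genes and 10 below, among the latter the elongation factor gene Supt5h at -0.73 and Paf1 at -0.65. RNA polymerase II subunits had a median of -0.22 over 13 genes (percentile 98.995), with 9 above the median of all genes and 4 below, among the latter Polr2i at -0.52. The cofactor and polymerase lists were at percentiles 82.5 and 91.9 without matching on expression. Relatives and adaptors of Nedd4 had a median of -0.19 over 7 genes (percentile 90.1), with the adaptor gene Ndfip1 at 28.1 and 16.8 RPKM (-0.71) and the ligase gene Itch at -0.59.

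Hosts of small nucleolar RNAs and other noncoding RNAs lay above matched genes, with a median of -0.12 over 15 genes (percentile 99.99). Beside Xist, the furthest of them were Malat1 at 187 and 120 RPKM (-0.64), Kcnq1ot1 and Neat1 (both -0.38), all lower, and the highest were Snhg12 (0.35) and Snhg1 (0.14). Structured noncoding RNAs had a median of -0.08 over 8 genes (percentile 99.9), spread from Rnu73b at -1.15 to Rpph1 at 0.45. Without genes of a mean depth over 2000 reads per base their percentile was 11.1. Ribosomal protein genes had a median of -0.26 over 76 genes (percentile 100), of which Rps16 was at least 2-fold lower (-1.15). Against lists matched on transcript length the ribosomal protein percentile was 57.8. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.34 over 58 genes (percentile 95.4), with Uqcrc1 at -0.59.

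Most markers of other cell types were low in both libraries, with exceptions among those of T cells and others below. Of 35 myeloid and 13 mast cell and basophil markers none reached a mean of 1 RPKM, and the highest myeloid marker stood at 1.07 RPKM in the Nedd4+/+ library. Of 19 markers of natural killer and innate lymphoid cells 1 did, Il2rb, at 1.41 and 0.995 RPKM. Of 24 T cell markers 5 did, with a median of -0.47 (percentile 2.34), led by Cd2 at 5.96 and 2.22 RPKM (-1.11) and Ctla4 (-0.64), while Thy1 was at 11.8 and 9.07 RPKM. Without a minimum level the T cell percentile was 88.8. Erythroid and megakaryocyte markers gave 4 tested genes with a median of -0.46, the globin genes Hba-a1 and Hba-a2 (both -0.53), Tfrc, the transferrin receptor that dividing cells also use (-0.40), and Car2 (0.03). Of the stromal and endothelial markers 2 were tested, with a median of -0.59, Vim at -0.69 and Pecam1 at -0.48, both of which B cells also express. None of the immunoglobulin constant genes was among the genes analysed here, and the immunoglobulin list had 0 tested genes. Of the 34 lists, 28 had at least 5 tested members. Of these 8 lay below and 8 above the range set for standing apart, the latter including the sex-linked list. By chance 1.4 would be outside it if the lists, and the genes within each list, were independent.

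The second comparison used the kb upstream of each gene, where transcription around promoters is read. Upstream levels were higher in the Nedd4-/- library across the genome, at genes of every level. Of 11837 windows with a mean of 0.2 RPKM or more, 2343 were at least 2-fold higher and 94 at least 2-fold lower, on a log2 scale with 0.1 RPKM added, and the median log2 ratio was 0.41. Among windows with a mean of 1 RPKM or more, by contrast, 10 were higher and 38 lower. Relative to the median of all windows tested 769 were higher and 672 lower, which moved the share of higher windows from 96.1% to 53.4%. The median difference between the libraries was 0.111 RPKM upstream of genes between 0.2 and 0.5 RPKM and 0.0889 RPKM upstream of genes between 10 and 30 RPKM. A single read pair in a window gives 0.0241 RPKM in the Nedd4+/+ and 0.0328 RPKM in the Nedd4-/- library. The same shift appeared within transcripts of genes silent in B cells: 1547 olfactory receptor, vomeronasal receptor, keratin-associated protein and defensin genes had a median of 0.0516 RPKM in the Nedd4+/+ and 0.141 RPKM in the Nedd4-/- library.

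**Figure D3:**
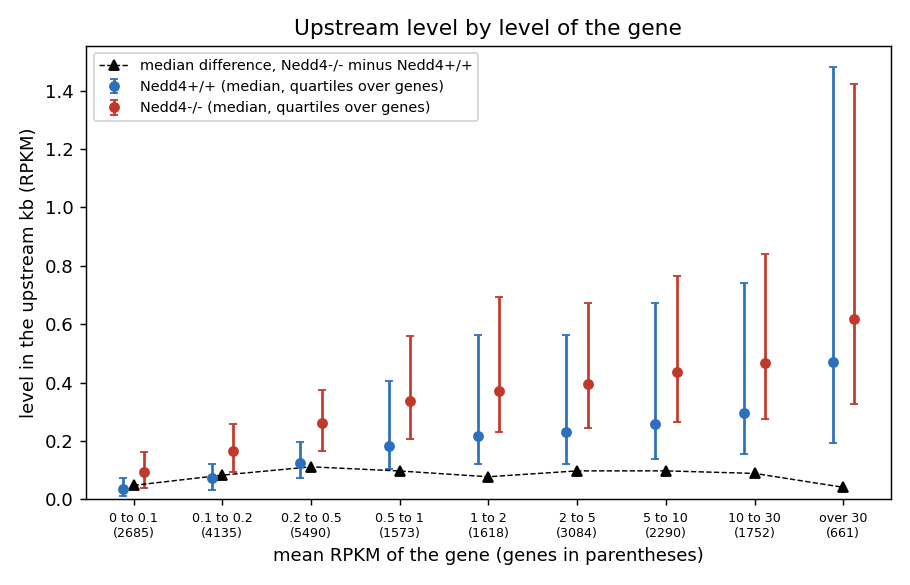
Median level in the upstream kb (y axis, RPKM) by the mean level of the gene (x axis, RPKM), with bars over the interquartile range of genes, for the Nedd4+/+ and Nedd4-/- libraries; triangles give the median difference between them. The difference runs from 0.0412 to 0.111 RPKM over the 9 classes.

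At single genes, the upstream windows with the highest log2 ratios among those with a mean of 1 RPKM or more were those of Havcr1, a receptor gene, at 0.702 and 2.55 RPKM (1.73), and Hjurp, a centromere chaperone gene, at 0.630 and 1.71 RPKM (1.31). They were followed by Rplp1 (1.07), Larp7 (0.96), Sfi1 (0.95), Rpl36al (0.93) and the near-identical pseudogenes Pisd-ps1 and Pisd-ps3 (both 0.91). The lowest were upstream of Dusp4, a phosphatase of MAP kinases, at 4.19 and 1.36 RPKM (-1.55), BC030307 (-1.39), Hist1h2be (-1.31), Csnk1a1 (-1.28), the kinase gene Csk (-1.22), Eif2a (-1.22), Trpt1 (-1.18) and Btla, an inhibitory receptor gene (-1.17). Upstream and gene log2 ratios were weakly related across the 11837 genes, with a Pearson correlation of 0.227 and a Spearman correlation of 0.232, and genes are not independent replicates.

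Upstream of genes known as off-target sites of AID, levels went both ways. Of 27 windows, 3 were at least 2-fold higher in the Nedd4-/- library: Btg2, an antiproliferative gene (1.37), the noncoding RNA gene Pvt1 (1.21) and Myc, at 0.185 and 0.492 RPKM (1.05). The counting interval for Myc, without the pseudocount, ran from 0.07 to 2.88. Of all windows 19.8% were at least 2-fold higher, and relative to the median of all windows 0 off-target windows were higher and 3 lower, those of Pim1, Il4i1 and Junb. The window of Pim1 was at least 2-fold lower, at 14.7 and 6.95 RPKM (-1.07), and those of Cd83, Cd79b and Bcl6 were at -0.15, 0.02 and 0.34. In all, 15 windows had a positive and 12 a negative log2 ratio. The list median was 0.19, at percentile 26.7 of matched random lists and below the 0.41 of all windows. Upstream relative to the gene's own ratio, the list median was 0.36 (order-statistic interval over genes 0.07 to 0.73, percentile 23.7), where random lists had 0.47 and all windows 0.55. Without windows that overlap another annotated gene the list kept 19 windows and lay at percentile 1.43, lower than matched windows.

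The other lists mostly did not stand apart upstream. Of 30 lists with at least 5 windows, immediate early genes lay above matched windows, with a median of 1.02 over 21 windows (percentile 99.5, and 94.6 with no upstream minimum), among them Ier3, Klf2 and Egr2. Of the 21, 14 lay above the median of all windows and 7 below. Relative to that median 2 were at least 2-fold higher, Ier3 and Klf2, and 2 lower, Ier2 and Junb. Histone genes lay below, with a median of -0.84 over 58 windows (percentile 0), and histone genes sit close together. By chance 1.5 of 30 lists would stand apart if the lists, and the genes within each list, were independent. CSR factors had an upstream median of -0.03 at percentile 5.01 and RNA exosome genes 0.21 at percentile 48.0.

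Genes near Nedd4 were compared with the rest, since the mice had a mixed B6 and 129 background and DNA linked to the targeted gene can differ in strain. Within 10 Mb of Nedd4, 1 of 80 tested genes passed the 2-fold rule, Myo1e, which encodes a myosin. This is 1.25% (interval 0.0316% to 6.77%), beside 1.28% or 119 of 9290 genes elsewhere. Relative to the median of all genes, 2 of the 80 passed it, Aqp9 and Dapk2, or 2.5% (interval 0.304% to 8.74%), beside 0.463% or 43 genes elsewhere.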

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

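The tests of an even background upstream, of the off-target explanation and of antibody-secreting cells, and both tests on chromosome 12, were chosen after the results were seen. The other tests rest on background, depth, GC content or length corrections that were also added after seeing the data, except the one on overlapping windows, which was planned.

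The first pattern is a higher level upstream of genes and in silent genes of the Nedd4-/- library. The median of 1547 olfactory receptor, vomeronasal receptor, keratin-associated protein and defensin genes was 0.141 RPKM there and 0.0516 RPKM in the Nedd4+/+ library, 2.73 times as much, a signal above that of the control library. Windows lying in other genes do not account for it, since 97.9% of 2-fold windows were higher without them. A higher even background, such as genomic DNA spread over the genome, may be a source, though its nature was not tested. Silent transcripts differed by 0.0894 RPKM and windows upstream of 7156 genes of 1 RPKM or more by a median of 0.0990 RPKM, which is close in size. With the level of silent transcripts taken off, the median log2 ratio was -0.06 over 5326 windows in place of 0.27. Of the 2-fold windows, 478 were then higher and 197 lower (70.8% higher) in place of 1050 and 69 (93.8%). The subtraction takes more from the Nedd4-/- library, so a fall in this share is by construction and only its size is informative. An accumulation of upstream transcripts at AID off-target genes could not have produced the shift in any case, with 27 of 11837 windows in that list. The shift was also present upstream of 12309 genes under 0.5 RPKM outside the list, by a median of 0.0847 RPKM (interval over genes 0.0827 to 0.0874). Whether upstream transcripts accumulated at the off-target genes themselves is a separate question. Their windows lay at percentile 26.7, or 1.43 without overlapping windows.

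The second pattern is the lower level of the lists of antibody secretion, the unfolded protein response, cholesterol synthesis, glycolysis and histones. All 5 stayed under percentile 2.5 against lists matched on GC content (medians -0.60 to -0.50 relative to random lists) or length (-0.61 to -0.52). This argues against GC content or length as the whole cause. All 5 also stayed there after the background was taken off (-0.61 to -0.41) and without genes of a mean depth over 2000 (-0.58 to -0.42). These settings could not decide the question, since both effects raise Nedd4-/- values, while the lists were lower. Equal depth gives a log2 ratio of 0.45. The background was 0.117 RPKM in the Nedd4+/+ and 0.244 RPKM in the Nedd4-/- library. A smaller share of antibody-secreting cells in the Nedd4-/- culture could lower the secretory lists. Relative to all genes, 4 identity genes of such cells had a median of -0.39, Igj at -0.84, Prdm1 at -0.60, Sdc1 at -0.18 and Slamf7 at -0.01, while Tnfrsf17, under the minimum level, was at 0.43; they belong to the secretion list itself, so this cannot be told apart from lower expression per cell. An effect of the genotype, of the mixed sex-linked signal or of the culture's state remains untested with 1 library per group.

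The third pattern is the higher level of Rpl36al, Mgat2, Dnaaf2, Pole2 and Klhdc2 on chromosome 12. A single duplicated segment would raise every gene in it, yet 2 expressed genes lying between them, 9330151L19Rik and Klhdc1, had log2 ratios of 0.01 and -0.08, though the window upstream of 9330151L19Rik, which overlaps another gene, was at 7.10 and 22.8 RPKM (1.67) and the next gene, Nemf, at 0.41. Reads from spliced copies elsewhere in the genome may be a source, since the median upstream log2 ratio of the 5 genes was 0.0331, but the windows of Rpl36al, Mgat2 and Pole2 overlap another gene, that of Rpl36al was at 8.04 and 15.4 RPKM (0.93), and upstream windows need not follow a gene's level, so this stays open. Before the 5 genes, Rps29 was at 1.16 and 1.01 RPKM, but the window upstream of it was at 198 and 267 RPKM (0.43). That window overlaps another gene, and its ratio is close to the 0.45 that equal depth gives. Its part in the pattern was not tested, nor was a strain difference between the libraries.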

How the results depend on the processing

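The alternatives of background, GC content, length, depth and sex chromosomes were tests chosen after seeing the data. No paired analysis was possible because each genotype has 1 library, which also rules out leaving out replicates and other splits. Keeping the line with the highest mean per symbol gave no value, since 0 symbols stand on more than 1 line. The cause of the changes below was not tested unless the setting itself shows it.

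The 5 lists of secretion, unfolded protein, cholesterol, glycolysis and histones lay at percentile 0 in each gene setting, the lowest value 10000 random lists can give. Over the 11 alternatives other than rescaling, which cannot move a percentile, their medians lay from -0.66 to -0.37 on the log2 scale relative to random lists, nearest to 0 with a pseudocount of 5. For the other lists, 266 of 289 gene percentiles and, over all lists, 228 of 235 upstream percentiles kept their call of standing apart or not. These counts include the rescaled settings, where the call was kept by construction. Nedd4 stayed lower in every setting run, at -1.91 with a pseudocount of 0.1, -0.86 with 5, and -1.23 after centring on the median or the trimmed mean. The 2-fold genes were 25 higher and 229 lower with a pseudocount of 0.1, 5 and 27 with 5, 26 and 21 after centring on the median and 26 and 21 on the trimmed mean. They were 4 and 10 at 3-fold and 34 and 1091 at 1.5-fold, by construction, and 7 higher with a minimum of 5 RPKM.

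Among gene lists, AID cofactors were at percentile 93.3 with a pseudocount of 5, 97.1 with no minimum, and 82.5 unmatched, 82.7 matched on GC content and 86.6 on length. RNA polymerase II was at 91.9, 92.6 and 85.1 in those last 3 settings. Ribosomal proteins were at 96.5 unmatched and 57.8 matched on length. Targets of p53 were at 87.1 with a minimum of 5 RPKM, 95.7 with background taken off and 97.3 matched on GC content. Structured noncoding RNAs were at 59.6 with no minimum, 78.4 matched on length and 11.1 without genes of depth over 2000. Immediate early genes were at 35.0 with no minimum and 39.0 with a minimum of 5 RPKM. T cell markers were at 3.53 with a pseudocount of 0.1, 2.66 with 5, 7.74 unmatched and 88.8 with no minimum, while LPS and NF-kappaB genes reached 99.4 there.

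Upstream, 165 windows were lower with a pseudocount of 0.02, 2 were higher and 12 lower with 1, and 4468 were higher with no minimum. With a minimum of 1 RPKM 10 were higher and 38 lower, after centring 769 and 672, and with background taken off 649 and 288. Without overlapping windows 35 were lower. AID off-target genes lay at percentile 1.43 and snoRNA hosts at 97.54 without overlapping windows, myeloid markers at 99.1 with a pseudocount of 1, ribosomal proteins at 98.5 with a minimum of 1 RPKM, and CSR factors at 0.970 unmatched. With no upstream minimum marginal zone and B1 genes were at 1.95 and immediate early genes at 94.6. The off-target comparison of upstream with gene ratios did not stand apart in any of its 6 alternative settings. Within 20 Mb of Nedd4 1.85% of 162 genes passed the 2-fold rule. Depth limits the windows, where 1 read pair is 0.0241 or 0.0328 RPKM.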

Other observations

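The gene groups in this part and their tests were chosen after the values were seen. These lists were built around genes already seen to be low and had no alternative settings, so their medians are given without those genes. Of fatty acid synthesis genes other than Scd1, Scd2 and Fads2, 9 of 10 tested lay below the median of all genes, with a median log2 ratio of -0.75. Beside Scd1 and Scd2, the desaturase gene Fads2 stood at 7.69 and 2.04 RPKM (-1.51) and Acly, which makes cytosolic acetyl-CoA, at 39.9 and 19.7 RPKM (-0.98). Srebf1, a regulator of these genes, was at -0.83. Genes of protein translocation, N-glycosylation and transport from the endoplasmic reticulum had a median of -0.60 over 33 genes, 29 of them below the median of all genes, leaving out Sec61a1, Sec24d, Rpn1 and Lman1. The translocon gene Sec61a1 was at 90.6 and 41.5 RPKM (-1.11), Rpn1, of the oligosaccharyltransferase, at -1.04, and the cargo receptor gene Lman1 at -1.18. All 19 cytosolic aminoacyl-tRNA synthetase genes other than Nars lay below the median of all genes, with a median of -0.68, while Nars was at -1.02 and Farsa at -0.34.

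Single genes outside the lists and the naming rule also differed. Slc16a3, a lactate exporter gene, stood at 7.87 and 0.941 RPKM (-2.19), Batf3, a transcription factor gene, at 6.17 and 1.29 RPKM (-1.65), Cd38, an ectoenzyme of B cells, at 5.18 and 1.29 RPKM (-1.43) and Satb1, a chromatin organizer gene, at 17.3 and 6.52 RPKM (-1.28). Hpgds, a prostaglandin D synthase gene, was at 2.45 and 6.17 RPKM (1.06) and Rgs1, a regulator of G protein signalling, at 0.950 and 2.98 RPKM (1.03).

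Of 4 genes known to escape X inactivation, too few for a list percentile, 2 were at least 2-fold lower in the Nedd4-/- library, Kdm5c (8.01 RPKM in that library) and Eif2s3x (-1.04). Kdm6a was at -0.93 and Ddx3x at -0.49, without passing the rule. All 4 lay below the median of all genes, in the library that also had almost no Xist. Sex-linked and genotype differences cannot be told apart here. The median of all X-linked genes was -0.32, within the range of the autosomes, -0.33 to -0.28.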
